A study of Homo sapiens with 96 samples.

How the data were processed

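RNA was measured in cultured MDA-MB-231 cells on 96 Affymetrix arrays, 64 from 2D culture and 32 from 3D culture. Per the labels, cells grown to 80% confluence were kept in low serum for 24 h, pre-treated for 30 min with 10 uM U0126 or its vehicle DMSO, and given 10 ng/ml EGF at 0 h. Array titles name 3 series, 2D03, 2D04 and 3D04, and the 2D repeat numbers follow the series. The time label 05h was read as 0.5 h. The labels do not say whether the repeats are separate cultures, so p-values here measure the spread between these samples.

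The values were the deposited table, presumed to be log2 signals because the submitters' processing notes name RMA, which returns log2 intensities per probe set. Neither the log base nor a centring is stated. Array medians lay between -0.06 and 0.03 and single values between -5 and 5.7, so each probe set had been centred on an unknown reference. Only differences between arrays are reported, and fold changes assume log2. The number of arrays limits the precision. Of 22930 probe sets, 524 were array controls and 19290 had 1 gene symbol in the annotation. Another 125 had several symbols and were left out, and 3292 were not listed, 2866 of them not array controls. The named probe sets covered 11874 genes.

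Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The 2D arrays were fitted with a mean for each of 31 groups (33 residual degrees of freedom). Times were averaged within an early (0.5 and 1 h), a middle (4, 8 and 12 h) and a late window (24 and 48 h). The 3D series had 1 array per arm and time after 0 h, so the times of a window served as its repeats (12 residual degrees of freedom). Differences between cultures came from a model of all arrays after 0 h with a term for each series and time. Errors are standard errors (SE) from these fits. The comparisons, windows, 20 gene lists, main alternatives and the rule for named genes were fixed before the data were examined. That rule took the 10 highest and 10 lowest called genes with the same sign in both repeats for each 2D comparison of U0126 with DMSO-EGF and of EGF with control, and the 5 highest and 5 lowest for the others. It added up to 4 members of each list with the smallest adjusted p, and always DUSP6, SPRY4, EGR1, FOS, FOSL1, CCND1, MYC and CYP1A1.

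A pair of choices departed from that plan after the values were seen to be centred ratios rather than levels. No filter on low values was used, where the plan kept genes with at least 2 arrays at the 40th percentile. Each gene was read from its probe set with the largest SD, where the plan took the highest mean. Both planned rules were run as alternatives. Of the genes, 4449 had several probe sets, and some of these disagreed. For SPRY4 in the late 2D window they ranged from -2.76 to 0.03, and the probe set at -2.76 was read. The largest-SD rule can favour the probe set that changes most, which can make fold changes larger.

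Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over all lists and comparisons of a culture, and again with an estimated correlation. The lists were immediate early genes, ERK output and feedback genes, EGFR ligands and growth factors, inflammatory cytokines and NF-kB targets, invasion and protease genes, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and FOXO-linked quiescence genes, receptor tyrosine kinases, cholesterol biosynthesis and SREBP targets, ATF4 and unfolded protein response genes, aryl hydrocarbon receptor targets, ribosome biogenesis and MYC targets, hypoxia and glycolysis genes, interferon-stimulated genes, mesenchymal and EMT genes, collagens and matrix genes, luminal epithelial markers, leukocyte markers and fibroblast markers. Of 329 list entries, 300 were measured.

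Whether repeat numbers pair the 2D samples was checked. Over 465 pairs of groups, the correlation of the repeats' deviations from their group means lay between 0.228 and 0.819 (median 0.635). The numbers therefore pair the samples, through the series label, and a fit with this replicate block was run beside each 2D result. The procedure was tested on simulated data with 67 of 11874 genes changed 2-fold. With the array numbers of the early 2D comparison of EGF with control, 89.6% of these were called with 0 false calls, or 100% with the block and 14 false calls. The share of false calls with the block was thus above the threshold set for the adjusted p. Genes that passed only with the block, and the larger counts it gave, are therefore less certain than those of the main fit. The alternatives were filters, probe set rules, median centring, quantile normalization, array weights, the replicate block, each 2D series alone, a joint fit of both cultures and each array or time left out. Chosen after seeing the data were a fit without the variance trend, the planned filter and probe set rule together, fits without a pair of arrays of low 5-prime actin signal, the values of the late 3D minus 2D difference at each time, and both ways of adjusting the pooled EGF lists.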

Results

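Gene expression was measured in MDA-MB-231 cells, a human breast cancer line, over 48 h after EGF was added with or without the MEK inhibitor U0126. MEK is the kinase that activates ERK. The 96 arrays came from 2D culture (series 2D03 and 2D04, 32 arrays each) and 3D culture (series 3D04, 32 arrays). The arms were untreated control, EGF, DMSO vehicle with EGF (DMSO-EGF), and U0126 with EGF. Each arm and time after 0 h had 2 arrays in 2D, 1 per series, and 1 array in 3D. In a 2D comparison each arm therefore had 4 arrays in the early window (0.5 and 1 h), 6 in the middle window (4, 8 and 12 h) and 4 in the late window (24 and 48 h). In 3D each arm had 2, 3 and 2 arrays. Values were differences from an unknown reference per probe set on a presumed log2 scale, so no absolute level is given.

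The first question was what the MEK inhibitor U0126 changed within 1 h in 2D cells that also received EGF. As U0126 was the only inhibitor used, effects of MEK inhibition and other effects of the compound cannot be told apart. EGR1 and FOS, both immediate early transcription factors, fell in U0126 against DMSO-EGF, each in both series. EGR1 was 3.06-fold lower (log2 -1.61, SE 0.27, adjusted p = 0.0091) and FOS was 3.04-fold lower (log2 -1.60, SE 0.29, adjusted p = 0.017). Of 20 immediate early genes 2 fell, or 4 adjusted over the list alone (median log2 -0.28, camera adjusted p = 4.2e-17, and adjusted p = 0.12 with an estimated correlation). Of 14 ERK output and feedback genes 0 passed, or 6 fell adjusted over the list alone (median log2 -0.29, camera adjusted p = 3.4e-17, and adjusted p = 0.00013 with an estimated correlation). In that list the ERK phosphatase DUSP6 stood at log2 -0.76, SE 0.21, adjusted p = 1, and the feedback inhibitor SPRY4 stood at log2 -0.62, SE 0.21, adjusted p = 1. In all 2 genes passed in limma, or 6 with the replicate block, 105 having an unadjusted p under 0.05. The block added the RNA-decay factor ZFP36 (log2 -1.08, SE 0.25, adjusted p = 4.3e-06 with the block) and the immediate early gene IER2 (-0.99, SE 0.28, adjusted p = 1.2e-05 with the block). On simulated data the block made more false calls than the threshold allows, so genes that passed only with it are less certain, here and below. Leaving out the 0.5 h DMSO-EGF array of repeat 1 or repeat 2, the 1 h DMSO-EGF or 1 h U0126 array of repeat 1, or the 0.5 h U0126 array of repeat 2 left 0 genes, and leaving out the 0.5 h U0126 array of repeat 1 left 1.

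By the middle window, ERK-linked genes were lower with U0126 in 2D by up to an order of magnitude. EGR1 fell 10.5-fold (log2 -3.39, SE 0.22, adjusted p = 3.7e-14), and the ERK phosphatases DUSP5 and DUSP6 fell 9.34-fold (-3.22, SE 0.14) and 6.60-fold (-2.72, SE 0.17). SPRY4 was 7.52-fold lower (-2.91, SE 0.17), the receptor tyrosine kinase EPHA2 3.36-fold (-1.75, SE 0.07), the AP-1 gene FOSL1 1.96-fold (-0.97, SE 0.09) and cyclin D1 (CCND1) 1.82-fold (-0.86, SE 0.10). Of 14 ERK output and feedback genes 12 fell, or 13 fell and 1 rose adjusted over the list alone (median log2 -1.07, camera adjusted p = 2.3e-37, and adjusted p = 1.2e-07 with an estimated correlation). The median of that list was -1.26 in series 2D04 and -0.94 in series 2D03. Of 20 immediate early genes 8 fell, or 11 adjusted over the list alone (median log2 -0.50, camera adjusted p = 2.6e-08, and adjusted p = 0.46 with an estimated correlation), among them FOS (log2 -1.42, SE 0.24). MYC, a growth regulator, stood at log2 -0.62, SE 0.25, adjusted p = 0.14, and passed with the replicate block (adjusted p = 6.8e-06).

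Also in the middle window, the cytokine IL11 fell 10.3-fold (log2 -3.36, SE 0.66, adjusted p = 0.0007), the matricellular gene CCN2 3.55-fold (-1.83, SE 0.25) and the Notch ligand JAG1 3.57-fold (-1.84, SE 0.37). Of 10 EGFR ligands and growth factors 3 fell, with the same number adjusted over the list alone (median log2 -0.45, camera adjusted p = 0.013, and adjusted p = 0.64 with an estimated correlation), with HBEGF at log2 -1.03, SE 0.22 and EREG at -0.66, SE 0.18. Of 14 invasion and protease genes 4 fell, or 5 adjusted over the list alone (median log2 -0.38, camera adjusted p = 4.6e-05, and adjusted p = 0.51 with an estimated correlation), with urokinase (PLAU) at log2 -1.52, SE 0.25 and its receptor (PLAUR) at -1.33, SE 0.13. Of 14 inflammatory cytokines and NF-kB targets 2 fell, with the same number adjusted over the list alone (median log2 -0.17, camera adjusted p = 0.049, and adjusted p = 1 with an estimated correlation). The chemokine CXCL8, at log2 -2.06, SE 0.90, adjusted p = 0.19, passed with the replicate block (adjusted p = 2.4e-07).

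The rising genes of the middle window were led by targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor. The monooxygenase genes CYP1A1 and CYP1B1 rose 7.75-fold (log2 2.96, SE 0.20, adjusted p = 1.4e-13) and 6.14-fold (log2 2.62, SE 0.37, adjusted p = 4.8e-06). Of 8 such targets 1 fell and 4 rose, with the same numbers adjusted over the list alone (median log2 0.15, camera adjusted p = 0.0043, and adjusted p = 0.38 with an estimated correlation), the 1 that fell being the receptor gene AHR itself (-0.46, SE 0.11, with -1.05 at 4 h, -0.13 at 8 h and -0.19 at 12 h). The neuropeptide receptor VIPR1 rose 3.87-fold (log2 1.95, SE 0.21) and the membrane glycoprotein GPNMB 2.39-fold (1.26, SE 0.16). Of 16 ribosome biogenesis and MYC targets 3 fell, with the same number adjusted over the list alone (median log2 -0.14, camera adjusted p = 0.0076, and adjusted p = 0.85 with an estimated correlation).

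In all 865 genes passed in the middle window of 2D, 254 higher and 611 lower, or 2315 with the replicate block, 2311 in series 2D03 alone and 1309 in series 2D04 alone. The repeat 1 arrays of U0126 at 8 and 12 h, both of series 2D03, had a low 5-prime against 3-prime signal of the actin control, a measure of RNA quality (log2 -1.26 and -1.08, against -0.36 to 0.31 on the other 94 arrays). Without this pair 341 genes passed, 302 of them among the 865, and with the replicate block 1025 passed. Leaving out single arrays gave 463 genes without U0126 8 h repeat 1, 477 without 12 h repeat 1, 1590 without 8 h repeat 2 and 1547 without 12 h repeat 2.

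**Figure D1:**
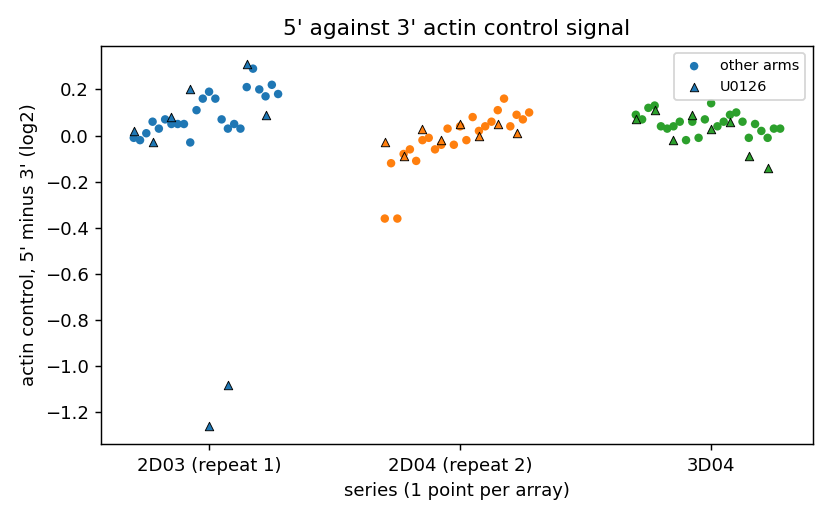
Actin control signal, 5-prime minus 3-prime (log2, y axis), of each array by series (x axis). A pair of U0126 arrays of series 2D03 stands at -1.26 and -1.08, and the other 94 arrays lie between -0.36 and 0.31.

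In the late window of 2D, genes of DNA replication and mitosis joined the ERK-linked genes among those lower with U0126. Cyclin E2 (CCNE2) fell 5.65-fold (log2 -2.50, SE 0.58, adjusted p = 0.0024) and the replication factor CDC45 4.42-fold (-2.15, SE 0.27). Of 25 G1/S and DNA replication genes 21 fell, or 24 adjusted over the list alone (median log2 -1.56, camera adjusted p = 1.4e-21, and adjusted p = 0.35 with an estimated correlation). The mitotic kinases CDK1 and AURKB fell 2.17-fold (log2 -1.12, SE 0.11) and 2.86-fold (-1.51, SE 0.20), and of 26 G2/M and mitosis genes 22 fell, or 25 adjusted over the list alone (median log2 -0.91, camera adjusted p = 7.5e-22, and adjusted p = 0.27 with an estimated correlation). This average covers unlike times: the median change of the G2/M list was -0.18 at 24 h and -1.62 at 48 h, and that of the G1/S list -1.22 and -1.85. Of 17 CDK inhibitors and FOXO-linked quiescence genes 6 rose, with the same number adjusted over the list alone (median log2 0.43, camera adjusted p = 0.025, and adjusted p = 0.34 with an estimated correlation), with CDKN1B, which encodes the CDK inhibitor p27, at log2 0.64, SE 0.17 and CDKN1C at 1.04, SE 0.28. Of 16 ribosome biogenesis and MYC targets 11 fell, or 12 adjusted over the list alone (median log2 -0.47, camera adjusted p = 8.4e-10, and adjusted p = 0.12 with an estimated correlation). MYC itself stood at log2 -0.47, SE 0.30, adjusted p = 0.42, and passed with the replicate block (adjusted p = 0.002).

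ERK-linked genes stayed low in the late window. DUSP6 fell 6.05-fold (log2 -2.60, SE 0.21), SPRY4 6.79-fold (-2.76, SE 0.21), FOSL1 4.43-fold (-2.15, SE 0.12), CCND1 2.28-fold (-1.19, SE 0.12) and EGR1 9.93-fold (-3.31, SE 0.27). Among 14 ERK output and feedback genes 11 fell, with the same number adjusted over the list alone (median log2 -1.38, camera adjusted p = 3.3e-26, and adjusted p = 3.2e-06 with an estimated correlation). Of 20 immediate early genes 4 fell, with the same number adjusted over the list alone (median log2 -0.34, camera adjusted p = 0.012, and adjusted p = 1 with an estimated correlation), while FOS stood at log2 -0.43, SE 0.29, adjusted p = 0.45. Of 10 EGFR ligands and growth factors 3 fell, with the same number adjusted over the list alone (median log2 -0.22, camera adjusted p = 0.025, and adjusted p = 0.67 with an estimated correlation). The interstitial collagenase MMP1 fell 6.11-fold (log2 -2.61, SE 0.74, adjusted p = 0.014), and of 14 invasion and protease genes 6 fell, or 7 adjusted over the list alone (median log2 -0.49, camera adjusted p = 6.9e-05, and adjusted p = 0.53 with an estimated correlation). Among rising genes, CYP1B1 was 46.4-fold higher (log2 5.54, SE 0.45, adjusted p = 1.3e-11), CYP1A1 21.9-fold (4.45, SE 0.25) and ID2, an inhibitor of DNA binding, 6.53-fold (2.71, SE 0.29). Of 8 aryl hydrocarbon receptor targets 5 rose, with the same number adjusted over the list alone (median log2 0.60, camera adjusted p = 1.6e-07, and adjusted p = 0.032 with an estimated correlation). In all 1481 genes passed, 772 higher and 709 lower, or 2952 with the replicate block, 1364 in series 2D03 alone and 3497 in series 2D04 alone.

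**Figure D2:**
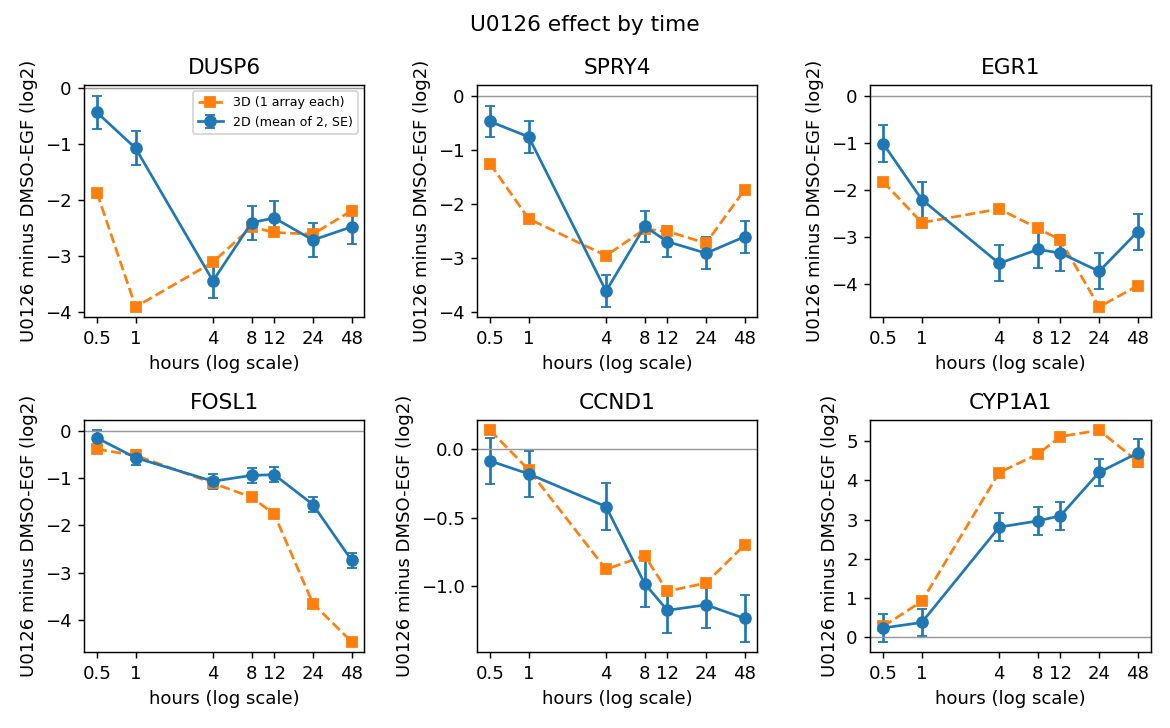
Difference between U0126 and DMSO-EGF (log2, y axis) against time in hours (log x axis) for 6 genes in 2D (blue, mean of 2 arrays per arm with SE) and 3D (orange, dashed, 1 array per arm). At 1 h DUSP6 stood at -1.08 in 2D and -3.91 in 3D, and at 48 h at -2.48 and -2.19.

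A second comparison asked what EGF alone changed against untreated cells. In 2D no gene passed in any window. The immediate early genes FOS and EGR1 stood at log2 0.26, SE 0.29, and 0.15, SE 0.27, in the early window, and DUSP6 at 0.20, SE 0.21, all with adjusted p = 1. In the middle window EGR1 stood at 0.45, SE 0.22, adjusted p = 1. There the 20 immediate early genes were higher as a list, of which 0 passed, with the same number adjusted over the list alone (median log2 0.16, camera adjusted p = 0.0027, and adjusted p = 0.91 with an estimated correlation). So were the 16 ribosome biogenesis and MYC targets, of which 0 passed, with the same number adjusted over the list alone (median log2 0.07, camera adjusted p = 0.0045, and adjusted p = 0.78 with an estimated correlation). The limma counts were 0 in each window, with 60, 223 and 55 genes at an unadjusted p under 0.05. They were also 0 with the replicate block and in either series alone.

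Because EGF raised 0 genes, the planned overlap with genes lowered by U0126 could not be tested. Across 11874 genes the early EGF and U0126 changes, which share no arm, had Pearson r = -0.05 and Spearman rho = -0.01 (genes are not independent replicates). The vehicle and pre-treatment comparisons in 2D also gave 0 genes in limma. For DMSO-EGF against EGF, EGR1 stood at log2 0.07, SE 0.27 in the early, 0.34, SE 0.22 in the middle and 0.20, SE 0.27 in the late window, and 57, 99 and 99 genes had an unadjusted p under 0.05. At 0 h, after pre-treatment alone, EGR1 stood at -0.17, SE 0.38 in U0126 against DMSO and at -0.28, SE 0.33 in DMSO against control, with 82 and 101 genes at an unadjusted p under 0.05.

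In the early window U0126 with EGF was also set against untreated cells, which received no EGF. The ERK output and feedback genes were lower as a list: of 14, 0 passed, or 5 fell adjusted over the list alone (median log2 -0.23, camera adjusted p = 6e-12, and adjusted p = 0.0019 with an estimated correlation). Of 20 immediate early genes 0 passed, or 4 fell adjusted over the list alone (median log2 -0.21, camera adjusted p = 7.2e-11, and adjusted p = 0.34 with an estimated correlation). EGR1 stood 2.62-fold lower (log2 -1.39, SE 0.27, adjusted p = 0.12) and passed with the replicate block (adjusted p = 0.00028). With the block 3 genes passed, against 0 in limma without it and 116 at an unadjusted p under 0.05.

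Untreated 2D cells drifted between 0 h (4 arrays) and 48 h (2 arrays) in low serum. Lanosterol synthase (LSS), an enzyme of cholesterol synthesis, rose 4.96-fold (log2 2.31, SE 0.58, adjusted p = 0.012), and EGR1 fell 6.82-fold (log2 -2.77, SE 0.33, adjusted p = 1.7e-06). The calcium-binding gene S100A4 rose 4.71-fold (log2 2.23, SE 0.45), the glycolytic aldolase ALDOC 4.49-fold (2.17, SE 0.31) and SPRY4 1.91-fold (0.93, SE 0.25). Of 14 cholesterol biosynthesis and SREBP targets 7 rose, or 13 adjusted over the list alone (median log2 1.23, camera adjusted p = 2.2e-14, and adjusted p = 0.3 with an estimated correlation). Of 26 G2/M and mitosis genes 5 fell, or 11 adjusted over the list alone (median log2 -0.52, camera adjusted p = 1.2e-08, and adjusted p = 0.78 with an estimated correlation). Of 16 ribosome biogenesis and MYC targets 5 fell, or 10 adjusted over the list alone (median log2 -0.41, camera adjusted p = 7.9e-08, and adjusted p = 0.25 with an estimated correlation). Of 15 ATF4 and unfolded protein response genes 2 fell, or 3 adjusted over the list alone (median log2 -0.41, camera adjusted p = 0.0036, and adjusted p = 1 with an estimated correlation). Of 16 hypoxia and glycolysis genes 3 rose, or 1 fell and 4 rose adjusted over the list alone (median log2 0.24, camera adjusted p = 0.0014, and adjusted p = 0.12 with an estimated correlation). Among 14 ERK output and feedback genes 2 rose, or 1 fell and 5 rose adjusted over the list alone (median log2 0.39, camera adjusted p = 0.0039, and adjusted p = 0.38 with an estimated correlation). In all 612 genes passed, 282 higher and 330 lower, or 1854 with the replicate block, and 130 without the 48 h control of repeat 2.

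In 3D culture U0126 lowered ERK-linked genes within the early window. DUSP6 fell 7.41-fold (log2 -2.89, SE 0.30, adjusted p = 2.7e-05), EGR1 4.81-fold (-2.27, SE 0.20), SPRY4 3.41-fold (-1.77, SE 0.22), CXCL8 5.48-fold (-2.46, SE 0.38) and MYC 2.17-fold (-1.11, SE 0.12). ID2 rose 2.59-fold (1.38, SE 0.25) and CYP1B1 2.58-fold (1.37, SE 0.27). Of 20 immediate early genes 10 fell, or 13 adjusted over the list alone (median log2 -0.61, camera adjusted p = 1.2e-35, and adjusted p = 2.5e-05 with an estimated correlation). Of 14 ERK output and feedback genes 8 fell, or 9 adjusted over the list alone (median log2 -0.75, camera adjusted p = 4.9e-31, and adjusted p = 0.0028 with an estimated correlation). In all 37 genes passed, 2 higher and 35 lower, against 22 without the 0.5 h arrays and 14 without the 1 h arrays.

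In the middle window of 3D, CYP1B1 rose 30.5-fold (log2 4.93, SE 0.22, adjusted p = 1.3e-10), CYP1A1 25.3-fold (4.66, SE 0.18) and the cytokine CSF1 4.91-fold (2.30, SE 0.16). DUSP5 fell 8.38-fold (-3.07, SE 0.18), DUSP6 6.60-fold (-2.72, SE 0.25), SPRY4 6.26-fold (-2.65, SE 0.18) and CCND1 1.87-fold (-0.90, SE 0.08). Among 14 ERK output and feedback genes 13 fell, with the same number adjusted over the list alone (median log2 -1.32, camera adjusted p = 4.4e-22, and adjusted p = 0.0092 with an estimated correlation). Of 14 invasion and protease genes 6 fell, or 8 adjusted over the list alone (median log2 -0.34, camera adjusted p = 5.4e-05, and adjusted p = 0.14 with an estimated correlation). Of 25 G1/S and DNA replication genes 14 fell, or 22 adjusted over the list alone (median log2 -0.34, camera adjusted p = 7.8e-09, and adjusted p = 0.54 with an estimated correlation). In all 1830 genes passed, 858 higher and 972 lower, against 880 without the 8 h arrays and 713 without the 12 h arrays.

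In the late window of 3D, the secreted glycoprotein STC1 fell 26.3-fold (log2 -4.71, SE 0.34, adjusted p = 4.7e-09), CXCL8 19.9-fold (-4.32, SE 0.38), EGR1 19.2-fold (-4.26, SE 0.20) and FOSL1 16.7-fold (-4.07, SE 0.18). CYP1B1 rose 70.0-fold (log2 6.13, SE 0.27), CYP1A1 29.4-fold (4.88, SE 0.22), ID2 21.0-fold (4.39, SE 0.25) and the bicarbonate transporter SLC4A4 14.2-fold (3.83, SE 0.23). Of 26 G2/M and mitosis genes 26 fell, with the same number adjusted over the list alone (median log2 -2.37, camera adjusted p = 6.1e-30, and adjusted p = 0.084 with an estimated correlation). Of 25 G1/S and DNA replication genes 23 fell, with the same number adjusted over the list alone (median log2 -2.13, camera adjusted p = 5e-22, and adjusted p = 0.17 with an estimated correlation). Among 14 ERK output and feedback genes 12 fell, with the same number adjusted over the list alone (camera adjusted p = 1e-09, and adjusted p = 0.084 with an estimated correlation). Of 16 hypoxia and glycolysis genes 10 fell, or 13 adjusted over the list alone (median log2 -0.82, camera adjusted p = 4.6e-06, and adjusted p = 0.52 with an estimated correlation). Of 14 cholesterol biosynthesis and SREBP targets 9 fell and 2 rose, or 10 fell and 2 rose adjusted over the list alone (median log2 -0.74, camera adjusted p = 0.00036, and adjusted p = 0.56 with an estimated correlation). In all 4641 genes passed, 2478 higher and 2163 lower.

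EGF against control in 3D gave 0 genes in limma in each window, with 372, 371 and 399 at an unadjusted p under 0.05. EGR1 stood at log2 0.14, SE 0.20, and FOS at 0.08, SE 0.09, in the early window, both with adjusted p = 1. Of 16 hypoxia and glycolysis genes 0 passed, with the same number adjusted over the list alone, in the middle window, where the list was lower (median log2 -0.20, camera adjusted p = 1e-09, and adjusted p = 0.27 with an estimated correlation). DMSO-EGF against EGF over the 7 times gave 0 genes in limma, with 351 at an unadjusted p under 0.05 and EGR1 at 0.12, SE 0.23, and 1 gene passed without the 48 h arrays.

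A direct comparison tested whether the U0126 effect differed between the cultures. The 3D arrays are 1 series, so culture and series cannot be told apart in any window. The SE and adjusted p therefore hold no spread between 3D series. In the early window DUSP6 fell 4.39-fold further in 3D (difference of log2 changes -2.13, SE 0.35, adjusted p = 0.00043), and the changes of the EGFR ligand HBEGF (-1.21, SE 0.18) and the Notch target HES1 (-1.15, SE 0.18) were also more negative. Of 14 ERK output and feedback genes 3 had a more negative change in 3D, or 7 adjusted over the list alone (median log2 -0.55, camera adjusted p = 8.5e-21, and adjusted p = 7e-06 with an estimated correlation). In all 8 genes differed, each with a more negative change in 3D, and 0 without series 2D04. In the middle window the cytokines CSF1 (2.23, SE 0.19) and IL11 (1.91, SE 0.29) and the growth factor TGFB2 (1.94, SE 0.35) had a more positive change in 3D, and STC1 (-1.95, SE 0.32) a more negative one. There 271 genes differed, 164 with a more positive and 107 with a more negative change in 3D. This count was 177 without the pair of 2D arrays of low 5-prime actin signal, 106 without series 2D03 and 1298 without series 2D04.

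In the late window, of 26 G2/M and mitosis genes 24 had a more negative change in 3D, or 25 adjusted over the list alone (median log2 -1.52, camera adjusted p = 4.4e-36, and adjusted p = 0.029 with an estimated correlation). Of 25 G1/S and DNA replication genes 13 had a more negative change in 3D and 1 had a more positive change in 3D, or 16 had a more negative change in 3D and 1 had a more positive change in 3D adjusted over the list alone (median log2 -0.54, camera adjusted p = 4.7e-11, and adjusted p = 0.24 with an estimated correlation). At 24 h the median difference was -1.89 for G2/M genes and -0.91 for G1/S genes, and at 48 h it was -1.17 and -0.13, values without a test because 3D has 1 array per arm and time. Of 16 hypoxia and glycolysis genes 12 had a more negative change in 3D, with the same number adjusted over the list alone (median log2 -1.09, camera adjusted p = 2e-20, and adjusted p = 0.0037 with an estimated correlation). Of 14 cholesterol biosynthesis and SREBP targets 10 had a more negative change in 3D, or 11 adjusted over the list alone (median log2 -0.84, camera adjusted p = 6.3e-16, and adjusted p = 0.0092 with an estimated correlation). FOSL1 differed by -1.92 (SE 0.25) and the cystatin CST1 by -3.40 (SE 0.54), while SLC4A4 differed by 2.77 (SE 0.28) and the complement gene C4B by 2.56 (SE 0.24). For DUSP6 the difference was 0.20, SE 0.35, adjusted p = 0.84, and for CCND1 0.35, SE 0.18, adjusted p = 0.26. In all 1209 genes differed, 511 with a more positive and 698 with a more negative change in 3D, against 775 under quantile normalization. In a fit with a U0126 effect per series, 1304 genes differed between 3D04 and the mean of the 2D series and 51 between 2D04 and 2D03. The early EGF effect differed between cultures at 0 genes in limma, with 182 at an unadjusted p under 0.05 and EGR1 at -0.01, SE 0.31.

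The cultures also shared part of their U0126 response. EGR1 and FOS, called in the early window of 2D, were lower in 3D too. Across 11874 genes the changes in 2D and 3D, which share no array, had Pearson r = 0.24 and Spearman rho = 0.06 in the early window, 0.62 and 0.45 in the middle window, and 0.81 and 0.68 in the late window (genes are not independent replicates). In the middle window 466 genes were called in both, 462 in the same direction, where independent lists would share 133. In the late window 1292 were called in both, 1282 in the same direction, where independent lists would share 579.

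**Figure D3:**
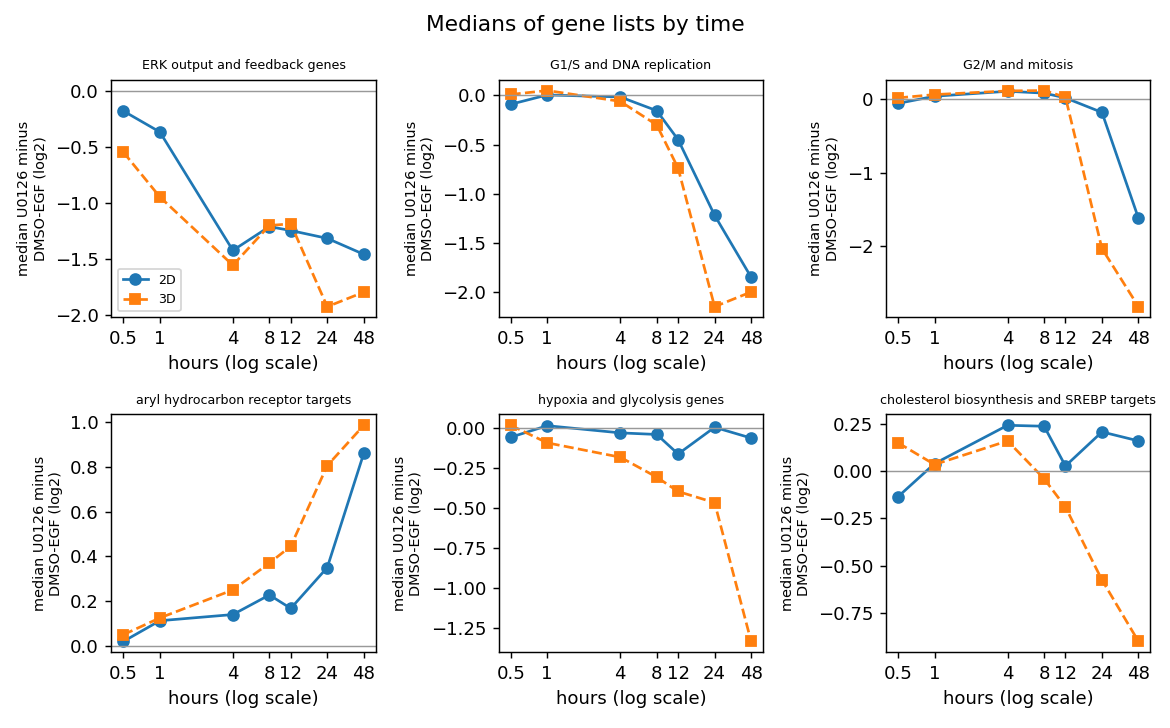
Median difference between U0126 and DMSO-EGF (log2, y axis) of 6 gene lists against time in hours (log x axis), in 2D (blue) and 3D (orange). At 24 h the G2/M list stood at -0.18 in 2D and -2.04 in 3D.

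**Figure D4:**
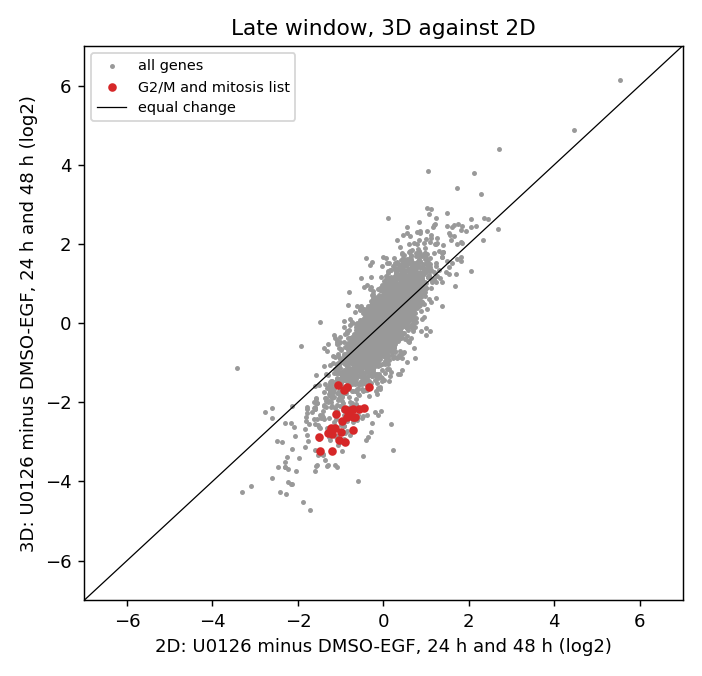
Late U0126 effect per gene in 3D (log2, y axis) against 2D (log2, x axis), each point a gene, with the line of equal change. The 26 G2/M and mitosis genes are in red, with a median difference of -1.52.

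Untreated cells of the 3D series (8 times) were set against those of the 2D series. NUPR1, a stress-response gene, was 11.1-fold lower in 3D (log2 -3.48, SE 0.15, adjusted p = 3.2e-14), the cysteine-forming enzyme CTH 7.95-fold (-2.99, SE 0.22) and the stress cytokine GDF15 7.59-fold (-2.92, SE 0.13). The hyaluronan-degrading CEMIP was 10.2-fold higher (log2 3.35, SE 0.20), the cadherin CDH11 4.21-fold (2.08, SE 0.10) and DUSP6 1.67-fold (0.74, SE 0.09). Of 15 ATF4 and unfolded protein response genes 15 were lower, with the same number adjusted over the list alone (median log2 -1.62, camera adjusted p = 1.6e-11, and adjusted p = 0.34 with an estimated correlation). Of 14 cholesterol biosynthesis and SREBP targets 13 were higher, with the same number adjusted over the list alone (median log2 0.47, camera adjusted p = 1.2e-05, and adjusted p = 0.34 with an estimated correlation). In all 6361 genes passed, 3091 higher and 3270 lower, against 4140 without series 2D03. With 1 series in 3D, culture and series cannot be told apart, and the 2D series differed from each other at 6261 genes in the same fit. Of 15 ATF4 and unfolded protein response genes in 2D04 against 2D03, 15 were lower, with the same number adjusted over the list alone (median log2 -0.53, camera adjusted p = 1.7e-05, and adjusted p = 0.34 with an estimated correlation).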

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

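The tests of the arrays of low RNA quality, of ERK output without EGF and of the interval of the EGF effect were chosen after the results were seen, and how the pooled EGF test was adjusted and read was changed after its result was seen.

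In the late window the G2/M and mitosis list had a more negative U0126 change in 3D than in 2D (median difference -1.52). The 2D series differed from each other in this effect at 51 genes, against 1304 between 3D04 and the mean of the 2D series, which argues against a difference of the size found between the 2D series as the whole cause. The spread of values on the 3D arrays stays open as a part of it, since quantile normalization left a share of 0.747 of the G2/M difference (-1.52 to -1.13). Culture in 3D may account for the remainder, but with 1 series in 3D, culture and series cannot be told apart. The 2D04 minus 2D03 difference of the list was -0.45.

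In the middle window of 2D the U0126 arrays of repeat 1 at 8 and 12 h stood at -1.26 and -1.08 in actin 5-prime minus 3-prime signal, outside the range of the control arrays (-0.36 to 0.21). RNA degradation could account for a part of the 865 genes. Without the pair their median change fell from 0.48 to 0.34, a share of 0.703, while all 865 kept their direction. These values cannot decide it, because the 865 were called with the pair included and both fits share the other arrays. The count fell from 865 to 341 genes without the pair, 302 of them among the 865, in a fit with fewer arrays. In other splits that part as many pairs in the block, the highest count was 2549 with the pair together and 369 with it apart. How much of the count is due to the pair stays open. MEK inhibition is consistent with series 2D04, which holds neither array and where the ERK output and feedback list had a median of -1.26, with 13 of 14 genes lower.

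No gene passed for EGF against control in limma. Too few arrays for changes of 2-fold is argued against by the fit itself for the early window of 2D only. There 98.8% of genes, and 17 of 20 immediate early genes, had a 95% interval of the change inside 2-fold. Smaller changes, the other windows and 3D were not covered, so too few arrays stays open for them. An EGF that had little activity, or arms that were mislabelled, stays open: with both EGF arms of the 3 series pooled the immediate early list had an early median of 0.0383, but its middle-window call changes with the adjustment (adjusted p = 0.017 over the 20 lists of the window, 0.0509 over all 60 tests). ERK output that was present without added EGF may account for it, since U0126 lowered the ERK output and feedback list against control by a median of -0.234. These data do not separate the explanations that remain, and 14 genes passed in the pooled middle window.

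In the early window 8 genes differed in their U0126 change between the cultures, tested as the difference itself, and 0 without series 2D04. Those named were DUSP6 (-2.13), HBEGF (-1.21), HES1 (-1.15), DUSP5 (-1.09), IER3 (-1.02) and MYC (-0.85), with 3D minus 2D differences on the log2 scale in parentheses. The list medians were -0.55 for ERK output and feedback genes and -0.12 for EGFR ligands and growth factors. As the 3D arrays are 1 series, these differences cannot be put down to culture.

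Between 4 and 12 h 271 genes differed in their U0126 change between 3D and 2D. The count was 106 without series 2D03, 1298 without series 2D04 and 177 without the pair of arrays of low actin signal. In a fit of U0126 minus DMSO-EGF per series and time, with whole series set against the others, 447 genes differed for 2D03 and 6 for 3D04. Series 2D03 holds the pair of arrays of low actin signal, which this fit included. The 447 therefore cannot be read as an ordinary difference between series. Either way, the 271 genes cannot be put down to culture. Differences were more positive in 3D for CYP1B1 (2.31), CSF1 (2.23), TGFB2 (1.94), IL11 (1.91), ID2 (1.75), CYP1A1 (1.71) and FOS (0.95). They were more negative for G0S2 (3D minus 2D -2.0), STC1 (-1.95), TMEM45A (-1.45), PTX3 (-1.43) and NDRG1 (-1.33), and the EGFR ligand list had a median of -0.075.

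In the late window 1209 genes differed in their U0126 change between 3D and 2D. Differences were more positive in 3D for SLC4A4 (2.77), C4B (2.56), IL11 (2.29), QKI (2.05), ABCA8 (1.90) and MYC (0.51). They were more negative for TMEM45A (-3.44), CST1 (-3.40), STC1 (-3.0), CST4 (-2.88), SPAG4 (-2.72), FOSL1 (-1.92) and EGR1 (-0.95). The cholesterol list had a median of -0.84 and the hypoxia list one of -1.09. Here too the 3D arrays are 1 series, so culture and series cannot be told apart.

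Of 2866 probe sets that the annotation does not list, 102 passed in the middle window of 2D U0126 against DMSO-EGF (32 higher and 70 lower) and 154 in the late window (82 higher and 72 lower), against 0 for EGF against control. In the group of 4 control arrays at 0 h, 0 of 17 genes tested had an array that stood apart from the others.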

How the results depend on the processing

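The tests without the variance trend, with the planned filter and probe set rule together, and without the pair of arrays of low 5-prime actin signal were chosen after the data were seen. Of the counts under alternatives, 360 stayed within 1.5 times the reported count and 46 did not. The 360 include counts of 0 that stayed at 0, as in the EGF and vehicle comparisons. This tally therefore does not measure how stable the counts above 0 were, for which the values are given below. List results kept direction and threshold in 409 cases, kept direction without passing in 71 and reversed in 1. These were lists that passed for U0126 against DMSO-EGF or for its 3D minus 2D difference. With an estimated correlation or the replicate block the same median was used, so the direction could not reverse there. The gene tally takes called genes of the naming rule and genes named in the text. Direction and threshold were kept in 4115 cases, the threshold was lost in 262 and newly passed in 27, and the direction reversed in 16. A gene that passed in neither fit counts as kept, and the counts of 2D04 against 2D03 are included. For U0126 against DMSO-EGF in 2D, the early count of 2 was 1 with the mean of probe sets, 6 with the replicate block, 4 in series 2D03 and 8 in series 2D04. The middle count of 865 was 491 with array weights, 2315 with the block, 341 without the low-signal pair, 2311 in series 2D03 and 1309 in series 2D04. The late count of 1481 was 2952 with the block and 3497 in series 2D04. U0126 against control in the early window, with 0 genes, gave 1 under quantile normalization, 1 with array weights and 3 with the block. The drift count of 612 was 1854 with the block. In 3D, array weights gave 2972 in place of 4641 late genes and 1 in place of 0 for DMSO-EGF against EGF. The early 3D minus 2D difference of 8 genes was 5 with the highest-mean probe set, 5 with the planned filter and probe set rule together, 13 under quantile normalization, 16 with array weights and 0 without series 2D04. The middle difference of 271 was 459 with array weights, 177 without the low-signal pair, 1298 without series 2D04 and 106 without series 2D03. The late difference of 1209 was 775 under quantile normalization and 767 with array weights. The EGF difference of 0 was 1 with array weights, and the culture count of 6361 was 4140 without series 2D03. With 1 array or time left out, counts ranged from 0 to 2 (early), 463 to 1590 (middle) and 1041 to 1407 (late) for U0126 in 2D, from 130 to 518 for the drift, and from 14 to 22, 713 to 1625 and 3782 to 3974 for U0126 in 3D. They ranged from 0 to 1 for DMSO-EGF against EGF in 3D and stayed at 0 for the 2D comparisons with 0 genes and for EGF in 3D. An arm left with 1 array was assumed to vary like the other groups. Reversed were IGF1R in the middle window (0.0217 with the highest-mean probe set, alone or with the filter), ZEB1 there (-0.94 with either, -0.19 with the mean of probe sets) and ERBB3 in the late window (-0.01 with either), where another probe set is read by construction, as for COL1A1 in the middle window (-0.06 with either). Where they did not pass, EGR1 and FOS changed sign: with an array or time left out, EGR1 ranged from -0.06 to 0.46 for DMSO-EGF against EGF late, from -0.36 to 0.03 for U0126 at 0 h and from -0.03 to 0.31 for early EGF in 3D, and FOS from -0.01 to 0.17 there. The EGF difference of EGR1 reversed to 0.0555 under quantile normalization and 0.09 without series 2D04. The late 3D minus 2D difference of the ERK output list reversed to 0.00222 under quantile normalization. For the other changes the cause was not tested. With the planned filter and probe set rule together, 683 of the 865 middle genes were among the 751 called and 1231 of the 1481 late genes among the 1334 called. Signal over background cannot be judged from centred values.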

Other observations

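The pooled EGF tests were chosen after the comparisons of EGF with control were seen, and their middle window and its adjustment after that result was seen. How splits are read for counts of 0 and for groups that are whole series was set after their values were seen.

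Of 16 interferon-stimulated genes in the late window of U0126 in 2D, 1 fell and 5 rose, or 1 fell and 6 rose adjusted over the list alone (median log2 0.22, camera adjusted p = 0.017, and adjusted p = 0.38 with an estimated correlation), with MX2 at log2 0.94, SE 0.13 and IFI6 at 0.72, SE 0.17. In 3D MX2 rose 2.83-fold (SE 0.16 on the log2 scale), and of 16, 2 fell and 6 rose, or 2 fell and 10 rose adjusted over the list alone (median log2 0.24, camera adjusted p = 0.053, and adjusted p = 0.27 with an estimated correlation). Among collagens and matrix genes the laminin chain LAMB1 fell 5.53-fold in 2D (log2 -2.47, SE 0.25) and 12.5-fold in 3D (-3.64, SE 0.24), and of 17 such genes 4 fell and 1 rose, with the same numbers adjusted over the list alone in 2D (median log2 -0.01, camera adjusted p = 0.19, and adjusted p = 0.91 with an estimated correlation).

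Among receptor tyrosine kinases in the late window of 2D, MET, the receptor of hepatocyte growth factor, fell (log2 -1.13, SE 0.19) and FGFR3 rose (0.98, SE 0.28), and of 16, 1 fell and 3 rose, with the same numbers adjusted over the list alone (median log2 0.07, camera adjusted p = 0.68, and adjusted p = 1 with an estimated correlation). Luminal epithelial markers moved both ways. The pioneer factor FOXA1 rose (log2 0.96, SE 0.14 in 2D and 1.76, SE 0.13 in 3D), and of 12 such markers 1 fell and 1 rose, with the same numbers adjusted over the list alone in 2D (median log2 0.07, camera adjusted p = 0.55, and adjusted p = 0.95 with an estimated correlation). Of 12 mesenchymal and EMT genes 1 rose, with the same number adjusted over the list alone in 2D (median log2 -0.07, camera adjusted p = 0.84, and adjusted p = 1 with an estimated correlation), and in 3D the matrix gene TNC fell 5.98-fold (-2.58, SE 0.25). Of 8 leukocyte markers in the late window of 2D 0 passed, with the same number adjusted over the list alone (median log2 0.05, camera adjusted p = 0.84, and adjusted p = 1 with an estimated correlation), and of 10 fibroblast markers 0 passed, with the same number adjusted over the list alone (median log2 0.01, camera adjusted p = 0.9, and adjusted p = 1 with an estimated correlation). In 3D the leukocyte marker PTPRC rose by 0.24 (SE 0.06, adjusted p = 0.015) in the middle and 0.24 (SE 0.08, adjusted p = 0.017) in the late window. The other leukocyte markers did not pass in either window of 3D. Their late changes lay between -0.195 (CD3E) and 0.035 (TYROBP), so PTPRC does not stand for the list. CD68, also a leukocyte marker, stood in the middle window of 2D at 0.25, SE 0.10, adjusted p = 0.11, and passed with the replicate block (adjusted p = 0.034), as did the fibroblast marker COL1A1 (0.43, SE 0.17, adjusted p = 0.14, or 0.022 with the block). That window holds the pair of U0126 arrays of low actin signal, at 8 and 12 h. CD68 stood at 0.04 at 4 h, 0.495 at 8 h and 0.225 at 12 h, and COL1A1 at 0.19, 0.605 and 0.495. These values cannot separate the marker changes from RNA quality. COL1A1 also reversed with the highest-mean probe set.

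Untreated cells of series 2D04 differed from those of 2D03. CXCL8 was 5.44-fold lower in 2D04 (log2 -2.44, SE 0.35), and SKP2, a regulator of the cell cycle, 3.35-fold higher (1.74, SE 0.13). Of 25 G1/S and DNA replication genes 1 was lower and 24 were higher, with the same numbers adjusted over the list alone (median log2 0.59, camera adjusted p = 2e-12, and adjusted p = 0.34 with an estimated correlation).

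With both EGF arms of the 3 series pooled against control, limma called 0 genes in the early window (234 at an unadjusted p under 0.05), 14 in the middle window (11 higher and 3 lower, 879 at an unadjusted p under 0.05) and 0 in the late window (305). The middle genes included RHOB, a small GTPase chosen after its values were seen (log2 0.71, SE 0.15, adjusted p = 0.033), and IER2 (0.29, SE 0.07, adjusted p = 0.044), while EGR1 stood at 0.44, SE 0.13, adjusted p = 0.21. The immediate early list had a median of 0.13 there, with adjusted p = 0.017 with an estimated correlation over the 20 lists of that window, the adjustment used first, and 0.0509 over all 60 tests of lists and windows. The call of the list changes with this choice, so a response of the list as a whole is neither shown nor excluded.

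Other splits of the same arrays tested whether chance can be excluded for the counts. Each split was fitted with 1 effect over the arrays of a window, so the real counts differ from those of the comparisons. For U0126 against DMSO-EGF in 2D, 1 of 34 splits, the real one, gave as many genes in the early window (real 2, highest other 0). In the late window 1 of 34 did (real 1491, highest other 1200, the split by series, with 2946 against 1178 in the block). These splits ignore the pairing by series, and those that part as many pairs in the block are too few for a share under 0.05. Whether chance can be excluded in these windows is therefore left undecided. In the middle window 6 of 100 drawn splits gave as many (real 850, highest of the others drawn 2260). Like those of the other windows, they ignore the pairing by series, so they cannot decide whether chance can be excluded. The split by series, which was not drawn, gave 3485, which points to a structure of the samples by series. Among splits that part as many pairs in the block, 3 of 100 gave as many (real 2244, highest other 2549). Both others kept the arrays of low 5-prime actin signal together, and the highest with them apart gave 369.

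Where the real count is 0, every split gives as many, so the splits decide nothing about chance. This covers EGF against control in 2D (34, 100 and 34 splits of the 3 windows, highest others 0, 1130 and 925, the last pair being the splits by series). It covers DMSO-EGF against EGF in 2D (34, 100 and 34 splits, highest others 0, 1 and 1523, the last by series, with 1444 for the split by series of the middle window, which was not drawn) and in 3D (100 splits, highest other 1). It also covers U0126 against control (34 splits, highest other 0), where with the block the real split gave 3 genes and the highest of 17 splits apart from it 0. In 3D the 10 splits of the middle window are too few for a share under 0.05, with real 1830 and highest other 0 for U0126, where 1 of 10 gave as many, and 0 and 0 for EGF, where 10 of 10 did. For the middle 3D minus 2D difference, fitted on U0126 minus DMSO-EGF per series and time, 2 of 84 splits gave as many (real 6, highest other 447). For the culture comparison 1 of 100 did (real 5019, highest other 2794). Times of 1 series are not independent of each other, and whole series allow 3 splits, too few for a share under 0.05. With whole series, the middle difference gave 6 genes for 3D04, 447 for 2D03 and 0 for 2D04 against the others.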
